A study of Mus musculus with 4 samples.

How the data were processed

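RNA from 4 sorted fractions of reprogramming mouse embryonic fibroblasts was profiled on Affymetrix arrays, 1 array per fraction. The series title calls them fractions of reprogramming cells, but no label states that the Oct4-negative cells shared a culture with the others. Per the labels' protocols, cells were fixed and stained inside before the sort, and total RNA of each fraction was recovered with the RecoverAll kit, amplified with the Ovation Pico WTA kit and biotinylated. Fixation and whole-transcriptome amplification act before the array and can change the level of a transcript according to its integrity, so the control probe sets of Gapdh and Actb at both transcript ends were read on each array. The deposited values are log2 levels of probe sets from robust multi-array average (RMA) processing, per the submitters' processing notes. The version of RMA is not given in the sources used here. In general, RMA subtracts background, quantile-normalizes the arrays and summarizes the probes of a set by median polish. The values ran from 1.31 to 14.4, with array medians of 4.55, 4.54, 4.52 and 4.49, which fits a log2 scale and a shared normalization. No scanner files were available, so the background correction could not be redone.

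The table held 45101 probe sets, of which 64 were controls and left out of the gene table. Genes were named through the platform annotation of these probes. Of the 45037 other probe sets, 34945 had 1 gene symbol, 932 had several and were not used for a gene, and 9160 were not listed there and stayed unnamed. Of the probe sets with 1 symbol, including 13 controls, 34754 had a gene identifier in the RefSeq table of assembly GRCm38.p6, which was used for names alone and changed 0 symbols. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 18193 genes, 9010 of them with several probe sets. The floor for a measured gene was the median of all values, 4.53, reached on at least 1 array by 11428 genes. The background ceiling was 2.94, the highest level of 27 bacterial control probe sets that stayed low on every array, taken as readings without a matching transcript. Where the dimmer level of a fold was at or below that ceiling, the fold was computed against the ceiling and is given as "at least".

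With 1 array per group no test was possible, and no p-value, standard error or confidence interval is given. Neighbouring gates were compared in 3 comparisons, and the other one joined the ends of the series. A gene was called higher or lower when the absolute log2 difference was at least 1 and the higher level reached the floor. As a rough gauge of measurement scatter, the median SD between probe sets of the same gene was 0.167, 0.172, 0.122 and 0.177 in the 4 comparisons, over 5708 genes with at least 2 probe sets reaching the floor. This scatter holds no variation between cultures or sorts. The named genes were set by a rule: in each comparison the 10 genes with the largest difference in each direction, leaving out uncharacterized genes and genes with another probe set, itself reaching the floor, going the opposite way, and up to 4 members of each fixed list past the size rule. Added to these were the 3 sorted factors with Sox2, Myc and Nanog, and the 10 genes with the largest total difference in each direction among those stepping one way at each gate. Any member of a fixed list could be named with its value.

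There were 33 gene lists, fixed before the data were examined, as were the comparisons, the size rule, the naming rule and the alternatives. They covered the sorted and other reprogramming factors, pluripotency (early or broad, late or naive), epithelial genes, mesenchymal regulators and adhesion, fibroblast matrix, contractile genes, TGF-beta targets, cell cycle, p53 and senescence, interferon response, cytokines and acute stress, immediate early genes, glycolysis, oxidative phosphorylation, DNA methylation and chromatin, germ line, Hox genes, Wnt targets, ribosomal proteins and housekeeping genes. Markers of keratinocytes, macrophages and leukocytes, endothelium, neural cells, skeletal muscle, cartilage and bone, adipocytes, erythroid cells, primitive endoderm and endoderm, mesendoderm and trophoblast were included as other cell types that a fraction could hold. A list's shift was the median log2 difference of its members reaching the floor on any array, for the 30 lists with at least 3 such members. Its percentile was taken among 10000 random lists of the same size, drawn from 20 bins of mean level. A list was called shifted outside the 2.5th to 97.5th percentile, as a description of these arrays and not as a test of the conditions.

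The size rule was tested on simulated data made from 18193 genes per comparison, with the scatter given above. In the comparisons of the Oct4, Klf4 and EpCAM steps and of the ends, it found 100%, 100%, 100% and 90.0% of genes set to a 2.5-fold difference. It found 100% at 3-fold and 4-fold in each, and 4.0%, 0%, 0% and 0% at 1.5-fold, while 0% of the unchanged genes were called. That last value was fixed by the setting, since the scatter is far below the 2-fold threshold. It gives no rate of false calls between cultures or sorts, whose variation was not simulated. In the list test, 20 of 20 simulated lists shifted by 0.5 lay above the random range in each comparison, and 0, 1, 0 and 1 of 20 unshifted lists lay outside it. The simulated differences held that scatter alone, while the measured differences had SDs across genes of 0.684, 0.909, 0.479 and 1.21 in the 4 comparisons. Random ranges of the real lists are therefore wider, and the simulation does not show how often a real shift of 0.5 would be called. Alternatives were the mean of all probe sets of a gene, leaving out probe sets with the suffix _s_at or _x_at, quantile, cyclic loess and median normalization of the deposited columns, a floor at the 75th percentile or none, a 3-fold threshold, probe sets in place of genes, a step of 0.25 in place of 0.5, and the mean of a list's members. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.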

Results

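Gene expression was measured in mouse embryonic fibroblasts (MEFs) undergoing reprogramming, the conversion of a differentiated cell toward a pluripotent state by introduced transcription factors. Per the labels, the cells were fixed, permeabilized, stained for 3 proteins and sorted into 4 fractions. The stains were Oct4 (encoded by Pou5f1) and Klf4, both reprogramming factors, and EpCAM (encoded by Epcam), an adhesion molecule of the epithelial cell surface. The fractions were Oct4-negative, Oct4+Klf4-negative, Oct4+Klf4+EpCAM-negative and Oct4+Klf4+EpCAM+. The labels do not give the day of sorting, the factors introduced, the way they were delivered, or whether the Oct4-negative cells came from the same culture as the others. Differences from that array can therefore include a difference between cultures. Each fraction was read on 1 array with 45037 probe sets besides controls, so no difference below has a replicate check, and the number of arrays limits the precision of each value. Median levels over all probe sets were 4.55, 4.54, 4.52 and 4.49 on the log2 scale, in the order of the fractions above. Between 75.9% and 76.7% of the 18193 named genes lay above the highest level of 27 bacterial control probe sets that stayed low on every array. Across the 11428 genes with a level at or above the median of all values on at least 1 array, which are not independent replicates, Pearson's r was 0.967 between the Oct4+Klf4+EpCAM-negative and Oct4+Klf4+EpCAM+ arrays. It was 0.936 between Oct4-negative and Oct4+Klf4-negative, 0.884 between Oct4+Klf4-negative and Oct4+Klf4+EpCAM-negative, and 0.794 between the ends of the series.

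The transcripts of the 3 sorted proteins were looked up first, as a check of the labels. Pou5f1 had a level of 7.59 in the Oct4-negative array and of 11.48, 11.66 and 11.70 in the Oct4-positive arrays, the first of these being 14.8-fold higher than the Oct4-negative level. Epcam had levels of 4.63, 5.20, 6.54 and 9.52 through the gates, and its level in the Oct4+Klf4+EpCAM+ array was 7.91-fold above the EpCAM-negative one. The 2 probe sets of Klf4 went opposite ways. The brighter probe set had levels of 7.32 and 6.24 in the Oct4-negative and Oct4+Klf4-negative arrays and of 10.20 and 10.60 in the Klf4-positive arrays, a difference of 15.6-fold at the Klf4 gate. The other had levels of 6.95, 5.69, 2.67 and 3.20 in the same order. Of the other reprogramming factors, Myc stayed between 9.74 and 10.08, while Sox2 was no higher than 3.15 and Nanog no higher than 2.67 on any array, below the level used here to call a gene measured. A probe set does not read a construct that lacks its part of the transcript. The low level of Sox2 therefore does not show that an introduced Sox2 was absent.

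**Figure D1:**
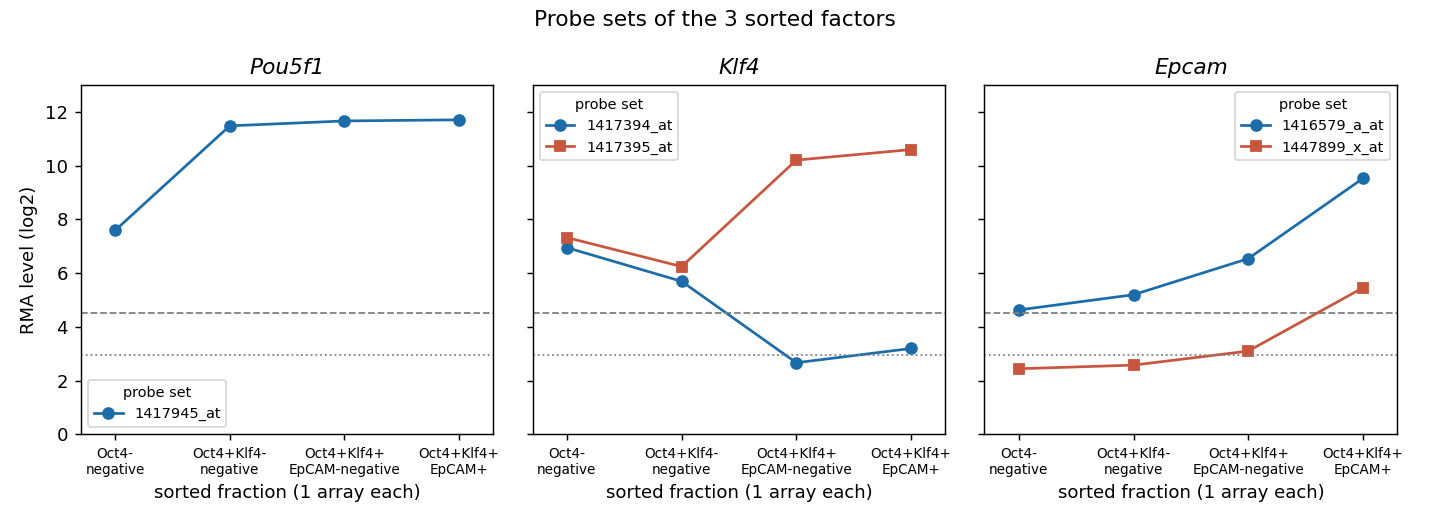
RMA level (log2) of each probe set of Pou5f1, Klf4 and Epcam in the 4 sorted fractions, 1 array each, with the dashed line at the floor of 4.53 and the dotted line at the background ceiling of 2.94. Pou5f1 steps up at the Oct4 gate and Epcam at the EpCAM gate, while the Klf4 probe sets part at the Klf4 gate, 1 at 10.20 and the other at 2.67.

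A gene was called higher or lower when its levels differed by at least 2-fold and the higher one reached the floor, the median of all values. By this rule the step at the Klf4 gate, from Oct4+Klf4-negative to Oct4+Klf4+EpCAM-negative, held the most genes of the 3 steps, 965 higher and 786 lower. The Oct4 step held 410 higher and 553 lower, and the EpCAM step 355 higher and 204 lower. Between the ends of the series, 1357 genes were higher and 1231 lower. A fold is given as "at least" where the dimmer level lay at or below the background ceiling. For a list of genes, the median log2 difference is given with its percentile among 10000 random lists of the same size and level, as a description of these arrays.

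**Figure D2:**
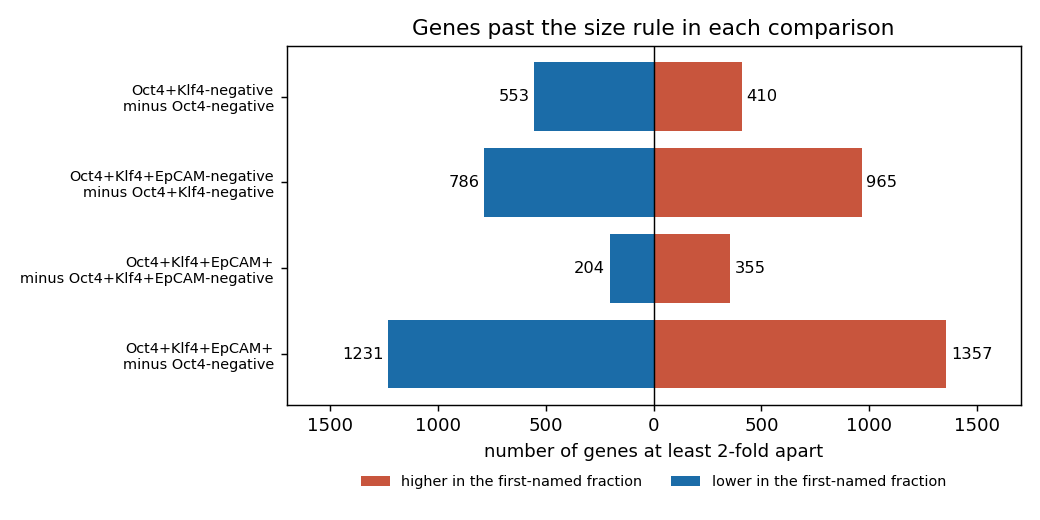
Number of genes at least 2-fold higher (right) or lower (left) in the first-named fraction of each comparison, 1 array per fraction. The bars of the Klf4 step (965 higher, 786 lower) are longer than those of the Oct4 step (410 and 553) and the EpCAM step (355 and 204).

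The first comparison asks how cells that stained for Oct4 without Klf4 differed from Oct4-negative cells, for which the labels give no Klf4 gate. Neural markers and Hox genes were higher in the Oct4+Klf4-negative array, and genes of fibroblast matrix and inflammation were lower. The largest difference was that of Cbln2, a secreted synapse organizer, 85.6-fold higher. The neurofilament genes Nefl and Nefm were 50.7-fold and at least 32.6-fold higher, and Elavl2, a neuronal RNA-binding protein, 46.1-fold. Matrix Gla protein (Mgp), a calcification inhibitor of connective tissue, was 17.6-fold lower, and Inhba, a subunit of the signalling protein activin, 15.1-fold lower.

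Among the other genes with the largest differences at the Oct4 step, the kinase gene Stk26 was 41.2-fold higher and Epha5, a receptor for ephrins in axon guidance, 30.9-fold. The protease gene Pcsk5 was at least 22.8-fold higher, and Nrcam, an adhesion molecule of axons, at least 23.7-fold. Serpini1, which encodes neuroserpin, was 28.7-fold higher and Lgi2 27.7-fold. On the lower side were Tnfaip2, a target of tumour necrosis factor signalling (21.8-fold), the serum-induced kinase gene Sgk1 (19.3-fold), Ccn3 (17.5-fold) and Btbd11 (14.7-fold). Ereg, a ligand of the epidermal growth factor receptor, was at least 12.8-fold lower, Gpnmb 14.2-fold and S1pr3, a receptor for a signalling sphingolipid, 14.1-fold.

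Of 9 measured neural markers, 5 were higher and 1 was lower (median log2 difference 1.69, above all 10000 random lists). The higher ones included Fabp7 (7.96-fold), a fatty acid binding protein of radial glia, Gap43 (7.39-fold), a growth cone protein, and Map2 (3.30-fold), a microtubule protein of dendrites, while Nes, the intermediate filament gene nestin, was 2.95-fold lower. In a separate list of 27 abundant neuronal transcripts, written later than the fixed lists, 12 reached the floor on any array, of which 2 were higher and 2 lower (median log2 difference 0.37, percentile 99.2). Hox genes, which set position along the body axis, had 10 of 24 measured members higher and 0 lower (median log2 difference 0.45, above all 10000 random lists). They included Hoxb6 (6.71-fold), Hoxb5 (6.39-fold), Hoxc10 (5.45-fold) and Hoxd8 (4.74-fold), while Hoxa3 and Hoxa13 had log2 differences of -0.79 and -0.85. The early or broad pluripotency list had 2 of 10 measured members higher (median log2 difference 0.35, percentile 98.5), Alpl (10.5-fold), which encodes alkaline phosphatase, and L1td1 (2.87-fold). Slc2a3, a glucose transporter, was 3.34-fold lower. That list's median was within the random range when all probe sets of a gene were averaged (0.23) and when genes below the floor were kept (0.00), as was the mean of its members (0.49).

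Fibroblast matrix genes had 14 of 33 measured members lower and 5 higher (median log2 difference -0.79, below all 10000 random lists). The collagen VI genes Col6a1 (14.8-fold), Col6a2 (12.5-fold) and Col6a3 (10.7-fold) were lower together with Bgn (12.3-fold), the proteoglycan biglycan, whereas Postn, which encodes periostin, was 7.22-fold higher and Dcn, the proteoglycan decorin, 3.63-fold higher. Cytokine and acute stress genes were lower in 9 of 10 measured members (median log2 difference -2.06, below all 10000 random lists), among them the chemokine genes Ccl2 (6.99-fold), Ccl7 (6.05-fold) and Cxcl1 (4.67-fold) and the prostaglandin synthase gene Ptgs2 (5.63-fold). Immediate early genes had 7 of 19 members lower (median log2 difference -0.56, below all 10000 random lists), including Ier3 (5.04-fold), Dusp1 (4.37-fold) and Hspa1b (3.19-fold). Of 13 TGF-beta targets, 6 were lower (median log2 difference -0.99, below all 10000 random lists), such as Ltbp2 (12.9-fold), Ltbp1 (4.15-fold) and Pmepa1 (3.90-fold). Mesenchymal regulators and adhesion genes were lower in 9 of 24 (median log2 difference -0.81, below all 10000 random lists), with Foxc2 (12.9-fold), Prrx2 (10.7-fold) and Snai1 (6.83-fold) at one end and Ncam1 (4.37-fold) and Zeb2 (3.78-fold) at the other. Contractile genes had 6 of 18 members lower (median log2 difference -0.63, below all 10000 random lists), including Acta2 (3.77-fold), smooth muscle actin, and Myl9 (2.95-fold), while Actg2 was 3.99-fold higher.

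Smaller shifts ran through the cell cycle list at the Oct4 step, where none of 37 members reached 2-fold but the list lay above the random range (median log2 difference 0.31, above all 10000 random lists). The chromatin list behaved alike (median log2 difference 0.32, percentile 99.98). In the p53 and senescence list, Cdkn2b and Cdkn2a, inhibitors of cell cycle kinases, were 2.29-fold and 2.07-fold lower (median log2 difference -0.29, percentile 0.02), while the mean of the members, -0.24, lay within the random range. Neither the epithelial list (median log2 difference 0.02, percentile 58.3) nor the keratinocyte markers (median log2 difference -0.09, percentile 19.9) lay outside the random range, although the keratin genes Krt19 and Krt18 were 4.90-fold and 3.72-fold lower. Of 4 measured macrophage and leukocyte markers, 2 were lower, Cd68 (3.52-fold) and Cd14 (2.68-fold), and the list's median of -0.98 became 0.048 when genes below the floor were kept. The Gapdh control probe sets, a sign of RNA integrity and amplification, differed more between the 3′ and 5′ ends in the Oct4+Klf4-negative array, by 1.3 on the log2 scale, than in the Oct4-negative array, by 1.0. Those of Actb did not, with differences of -0.052 and -0.059.

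The second comparison asks what distinguished cells that stained for Oct4 and Klf4 without EpCAM from cells that stained for Oct4 without Klf4. The labels give no EpCAM gate for the Oct4+Klf4-negative cells. Keratinocyte, epithelial and early pluripotency genes were higher in the Oct4+Klf4+EpCAM-negative array, and fibroblast matrix and contractile genes were lower. Fgf4, a growth factor gene of pluripotent cells, was 40.4-fold higher, and Sall4 and Lin28a, 2 further genes of pluripotent cells, 12.6-fold and at least 4.49-fold. Pkp1, a plakophilin of desmosomes, was 24.5-fold higher, and the embryonic globin gene Hbb-y at least 64.5-fold. Postn was 23.3-fold lower and Fbn2, a fibrillin of elastic fibres, 25.5-fold lower.

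Also among the largest differences at the Klf4 step were the metal transporter gene Slc39a8 (at least 44.9-fold), the cytochrome P450 genes Cyp2s1 (35.6-fold) and Cyp4f39 (28.7-fold), Ms4a4b (35.1-fold), Popdc3 (31.7-fold) and the milk casein gene Csn1s1 (31.6-fold). Laptm5, a lysosomal protein of blood cells, was 28.0-fold higher by its brightest probe set, and each of its 3 probe sets reaching the floor was higher, by a log2 difference of at least 1.36. All of these can read several transcripts, and the probe set without that property, below the floor, gave -0.45. On the lower side, Itga1, a collagen-binding integrin, was 37.5-fold lower, Ptx3, a soluble pattern recognition protein, 36.5-fold, and Col11a1 at least 17.3-fold. Several genes that had been higher at the Oct4 step were lower again: Epha5 (at least 35.4-fold), Nefm (28.6-fold), Pcsk5 (at least 22.8-fold), Cbln2 (27.3-fold) and Ldb2, a cofactor of LIM domain proteins (at least 20.6-fold).

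Keratinocyte markers were higher in 16 of 20 measured members and lower in 0 (median log2 difference 2.29, above all 10000 random lists). Besides Pkp1, these included Krtdap (17.7-fold), a protein of differentiating keratinocytes, Itgb4 (11.9-fold), the integrin of hemidesmosomes, and the keratin genes Krt14 (8.54-fold) and Krt6b (at least 7.43-fold). Trp63, which encodes the epidermal regulator p63, did not reach the floor on any array, nor did the markers Krt15, Col17a1 and Lor. The markers Krt5, Krt10 and Ivl had log2 differences of -0.23, -0.25 and -0.23. Epithelial genes were higher in 16 of 31 and lower in 0 (median log2 difference 1.06, above all 10000 random lists), among them Krt8 (11.8-fold), the desmosomal genes Dsp (9.59-fold) and Dsc2 (at least 9.44-fold), and Cdh1 (9.49-fold), which encodes E-cadherin. In the early or broad pluripotency list, 7 of 10 measured members were higher and 1 was lower (median log2 difference 1.36, percentile 99.98), L1td1 by 15.7-fold and, in the other direction, Alpl by 2.37-fold. The late or naive pluripotency list did not shift (median log2 difference 0.20, percentile 75.9), and 15 of its 24 members on the array, including Nanog, Esrrb, Zfp42, Dppa3 and Prdm14, did not reach the floor anywhere. Of the 9 measured members, Nr0b1, a nuclear receptor of pluripotent cells, was at least 10.2-fold higher, Lefty2, an antagonist of Nodal signalling, 2.02-fold higher and the transcription factor gene Tbx3 2.86-fold lower.

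Of 9 neural markers, 4 were higher and 2 lower (median log2 difference 0.27, percentile 85.3). Tubb3, a neuronal tubulin, was 19.8-fold higher, Stmn2, a microtubule regulator of growing axons, 18.9-fold, and Sox1, a neural transcription factor, 16.5-fold, while Gap43 and Map2 were 6.73-fold and 3.82-fold lower. Trophoblast genes had 6 of 11 members higher (median log2 difference 1.27, percentile 99.96), including the transcription factor genes Hand1 (6.62-fold), Tfap2c (6.15-fold) and Tead4 (5.83-fold). Of the 16 trophoblast genes on the array, 5 also belong to other lists. The shifts of this list, here and in the later comparisons, are therefore not independent of those lists. Endothelial markers had 4 of 6 members higher and 1, Egfl7 (2.78-fold), lower (median log2 difference 1.82, percentile 99.94). The higher ones included Cldn5 (9.28-fold), Flt1 (5.79-fold) and Tek (3.32-fold), and 10 others of the list, including Pecam1, Cdh5 and Kdr, did not reach the floor.

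Of 33 fibroblast matrix genes, 22 were lower and 4 higher (median log2 difference -1.45, below all 10000 random lists). The lower ones included Thbs1 (13.9-fold), which encodes thrombospondin, Thy1 (9.46-fold), a surface marker of fibroblasts, and Col1a2 (8.27-fold), while Col6a3 (8.89-fold) and Dcn (5.12-fold) were higher. Contractile genes were lower in 10 of 18 and higher in 2 (median log2 difference -1.04, below all 10000 random lists), with Ccn1 (8.97-fold) and Ccn2 (8.49-fold), targets of the YAP pathway, and Acta2 (6.16-fold). Mesenchymal regulators had 6 of 24 members lower and 3 higher (median log2 difference -0.34, percentile 0.06), Zeb2 (7.39-fold) and Cdh2 (3.95-fold), which encodes N-cadherin, against Foxc2 (5.40-fold) and Itgb3 (3.80-fold). The mean of those members, -0.26, lay within the random range. Hox genes were lower in 9 of 24 (median log2 difference -0.79, below all 10000 random lists), including Hoxb5 (3.59-fold), Hoxd10 (3.19-fold) and Hoxb6 (2.54-fold), and the median lay within the random range with the floor at the 75th percentile of all values (-0.90). Of the cytokine and acute stress genes, 3 of 10 were lower (median log2 difference -0.52, percentile 0.61), Csf1 (15.2-fold), Ccl7 (4.99-fold) and Cxcl1 (4.10-fold), and Ptgs2 was 3.24-fold higher. That median lay within the random range with the floor at the 75th percentile (-0.52) or with genes below the floor kept (-0.056). The p53 and senescence list was shifted down (median log2 difference -0.51, below all 10000 random lists), with Fas (2.78-fold) and Pmaip1 (2.30-fold) past 2-fold and Igfbp5 (3.43-fold) the other way, while the mean of its members, -0.29, lay within the random range. Gapdh 3′ and 5′ control probe sets differed by 1.3 on the log2 scale in the Oct4+Klf4-negative array and by 1.0 in the Oct4+Klf4+EpCAM-negative array, and those of Actb by -0.052 and -0.057. The primitive endoderm and endoderm list was shifted down (median log2 difference -0.45, percentile 1.05), but its median was 0.028 when genes below the floor were kept.

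The third comparison asks how cells that stained for EpCAM differed from those that did not within the Oct4 and Klf4 double-positive cells. Epithelial genes and keratinocyte markers were higher in the Oct4+Klf4+EpCAM+ array, and the mesenchymal regulators Zeb1 and Zeb2 and matrix genes were lower. Rab25, a small GTPase of epithelial recycling endosomes, was 17.7-fold higher, and the tight junction genes Cldn7 and Cldn4 13.4-fold and at least 6.96-fold. Zeb1 and Zeb2, repressors of E-cadherin, were 15.2-fold and at least 4.93-fold lower, and Vim, the intermediate filament gene of mesenchymal cells, 5.59-fold lower from a level of 11.50. Only 8 genes were higher and 3 lower by 8-fold or more, against 153 and 76 at the Klf4 step.

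Other genes with the largest differences at the EpCAM step were Mal2 (at least 11.5-fold), a protein of apical transport, Prom2 (12.4-fold), the membrane protease gene Tmprss4 (10.8-fold), Aldh3b2 (8.86-fold), Ano9 (8.57-fold), Mpzl2 (8.41-fold) and the chloride channel subunit gene Lrrc8e (7.91-fold). Lower were Efemp1 (8.67-fold), an extracellular glycoprotein, Nts (8.63-fold), which encodes the peptide neurotensin, Grem1 (6.59-fold), an antagonist of bone morphogenetic proteins, Scg5 (5.72-fold), Ncam1 (5.29-fold), Fabp7 (5.15-fold) and the neurotrophin receptor gene Ntrk3 (5.12-fold).

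Epithelial genes were higher in 23 of 31 measured members and lower in 0 (median log2 difference 1.88, above all 10000 random lists). Past Rab25 and the claudins, they included the splicing regulator gene Esrp1 (6.90-fold) and the transcription factor genes Grhl2 (6.17-fold) and Ovol1 (4.27-fold), and Cdh1 was 4.04-fold higher. Keratinocyte markers were higher in 14 of 20 and lower in 0 (median log2 difference 1.70, above all 10000 random lists), with Krt17 (7.48-fold), Krt6a (5.78-fold) and Lypd3 (5.24-fold), while Krtdap and Itgb4 had log2 differences of 0.44 and 0.25. Trophoblast genes had 4 of 11 members higher (median log2 difference 0.67, percentile 99.99), among them Elf5 (4.41-fold) and Tfap2c (2.87-fold). Early or broad pluripotency genes had 3 of 10 higher and 0 lower (median log2 difference 0.50, percentile 99.8), Lin28a (3.26-fold), the DNA methyltransferase gene Dnmt3b (3.22-fold) and Sall4 (2.54-fold). No member of the late or naive list passed the rule (median log2 difference 0.16, percentile 85.3).

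Matrix genes were lower in 12 of 33 measured members and higher in 0 (median log2 difference -0.89, below all 10000 random lists), including Postn (4.64-fold), Col5a2 (4.61-fold) and Col3a1 (4.29-fold). Mesenchymal regulators and adhesion genes had 9 of 24 lower (median log2 difference -0.63, below all 10000 random lists), Cdh2 (3.79-fold) and Snai2 (3.32-fold) besides those named above. Hox genes were lower in 3 of 24 (median log2 difference -0.42, below all 10000 random lists), Hoxc8 (2.48-fold), Hoxb6 (2.24-fold) and Hoxb5 (2.22-fold), and the median lay within the random range with the floor at the 75th percentile (-0.34). The neural markers Fabp7 (5.15-fold) and Gap43 (2.56-fold) were lower (median log2 difference -0.23, percentile 2.11 for the list). Immediate early genes were shifted up (median log2 difference 0.43, above all 10000 random lists) with Hspa1a (2.08-fold), a heat shock protein, past 2-fold, and Fos, 2.32-fold lower, the other way. Contractile genes were lower in 3 of 18 (median log2 difference -0.16, percentile 1.28), Cnn3 (3.56-fold), Ccn1 (2.59-fold) and Acta2 (2.10-fold), a shift that lay within the random range with the floor at the 75th percentile (-0.061) or with all probe sets of a gene averaged (-0.13). In the p53 and senescence list 2 genes were lower, Igfbp5 (4.64-fold) and Fas (2.06-fold) (median log2 difference -0.23, percentile 0.04). The primitive endoderm and endoderm list had 2 of 6 members lower (median log2 difference -0.78, below all 10000 random lists), and its median was 0.059 when genes below the floor were kept. Wnt targets were shifted down (median log2 difference -0.27, percentile 2.13) with 1 member lower. No member passed 2-fold in the endothelial markers (median log2 difference 0.46, percentile 99.5), glycolysis (median log2 difference 0.10, percentile 99.3), the cell cycle (median log2 difference 0.06, percentile 98.5) or oxidative phosphorylation (median log2 difference -0.11, percentile 0.54), although these medians lay outside the random range. The means over members of the last 2 lists, 0.058 and -0.10, lay within it, as did the cell cycle median without probe sets of shared sequence (0.036).

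The fourth comparison joins the ends of the series and asks how far the Oct4+Klf4+EpCAM+ cells stood from the Oct4-negative cells. Epithelial, epidermal and early pluripotency genes were higher, and the fibroblast matrix was lower almost throughout. Alox12b, a lipoxygenase of the epidermal barrier, was at least 158-fold higher, Lama3, a laminin chain of epithelial basement membrane, 82.1-fold, the water and glycerol channel gene Aqp3 82.0-fold and Cdh1 77.2-fold. Mgp was 84.9-fold lower, Cav1, the main protein of caveolae, 83.8-fold, and the type I collagen genes Col1a2 and Col1a1 68.0-fold and 66.8-fold.

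The remaining genes with the largest differences between the ends were Ly6g6c (77.0-fold), Cyp4f39 (75.2-fold), the transcriptional cofactor gene Eya2 (at least 59.0-fold), the mucin-type glycosyltransferase gene Gcnt3 (at least 57.8-fold), Cyp2s1 (72.0-fold) and Sox1 (at least 68.2-fold) on the higher side. On the lower side were Loxl1 (76.0-fold), a crosslinking enzyme of elastin, the cytochrome P450 gene Cyp1b1 (72.0-fold), Fhl1 (63.6-fold), the Wnt antagonist gene Sfrp2 (53.4-fold), Efemp1 (52.3-fold) and Bgn (49.7-fold).

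Fibroblast matrix genes were lower in 31 of 33 measured members (median log2 difference -3.38, below all 10000 random lists), and the 1 higher member was Dcn, 18.7-fold higher. Mesenchymal regulators and adhesion genes were lower in 17 of 24 (median log2 difference -2.14, below all 10000 random lists), with Zeb1 (43.2-fold) and Cdh2 (17.6-fold), and the integrin gene Itgb3 (3.47-fold) went the other way. Contractile genes were lower in 13 of 18 (median log2 difference -1.51, below all 10000 random lists), with Acta2 (48.7-fold) and Ccn1 (37.9-fold). Cytokine and acute stress genes were lower in 8 of 10 (median log2 difference -2.66, below all 10000 random lists), with Csf1 (33.7-fold) and Cxcl1 (19.3-fold). Of 13 TGF-beta targets, 7 were lower and 3 higher (median log2 difference -1.56, below all 10000 random lists), Ccn2 (35.0-fold) and Inhba (25.9-fold) against Bhlhe40 (4.21-fold). In the p53 and senescence list 6 of 20 genes were lower (median log2 difference -0.74, below all 10000 random lists), including Fas (6.65-fold), Cdkn2b (4.14-fold), Cdkn2a (3.95-fold) and Mdm2 (3.06-fold), while Cdkn1a, which encodes the p53 target p21, had a log2 difference of -0.18.

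Epithelial genes were higher in 25 of 31 (median log2 difference 2.82, above all 10000 random lists), with Krt8 (56.1-fold) and Crb3 (45.9-fold), and keratinocyte markers in 16 of 20 (median log2 difference 3.88, above all 10000 random lists), with Pkp1 (60.6-fold) and Krtdap (46.0-fold). No member of either list was lower. Early or broad pluripotency genes were higher in 8 of 10 (median log2 difference 2.40, above all 10000 random lists), with Fgf4 (54.9-fold), L1td1 (50.9-fold), Sall4 (42.7-fold) and Lin28a (14.5-fold). Of 9 measured late or naive pluripotency genes, 2 were higher (median log2 difference 0.55, percentile 94.2), Nr0b1 (at least 9.40-fold) and Mkrn1 (2.54-fold). Trophoblast genes were higher in 7 of 11 (median log2 difference 2.93, above all 10000 random lists), with Tfap2c (15.4-fold) and Hand1 (11.5-fold). The chromatin list was shifted up (median log2 difference 0.33, percentile 98.6), with Tet2 (6.61-fold) and Dnmt3b (5.04-fold) higher and Tet1 (3.94-fold) lower, but its mean over members, 0.41, and its median with all probe sets of a gene averaged, 0.25, lay within the random range. Hox genes had 2 of 24 members higher and 6 lower (median log2 difference -0.33, percentile 2.10). That median became 0.53 with the floor at the 75th percentile and lay within the random range after quantile (-0.28) or loess (-0.27) normalization and with all probe sets of a gene averaged (-0.27), as did the mean of the members (-0.38).

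Some differences ran one way through the gates. Matrix levels were lower at each gate, with list medians of 9.30, 8.62, 6.15 and 5.22, while epithelial levels, with medians of 4.07, 4.40, 5.53 and 8.04, were higher at the Klf4 and EpCAM gates and lay within the random range at the Oct4 gate. Over all genes, 64 were higher and 85 lower by at least 0.5 on the log2 scale at each of the 3 steps, more than in any other of the 12 orders of the arrays. The next order, with the first 2 arrays exchanged, gave 54 and 57. Genes higher at each step included Alox12b, Aqp3, Cdh1, Cyp4f39, S100a14, Grb7, Slc7a3, Mal, Arhgef16 and the receptor kinase gene Erbb3, with total differences from at least 158-fold for Alox12b to 37.4-fold for Erbb3. Genes lower at each step included Mgp, Cav1, Cyp1b1, Col1a2, Col1a1, Fhl1, Sfrp2, Acta2, the matrix protein gene Tnc and Zeb1, from 84.9-fold for Mgp to 43.2-fold for Zeb1.

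**Figure D3:**
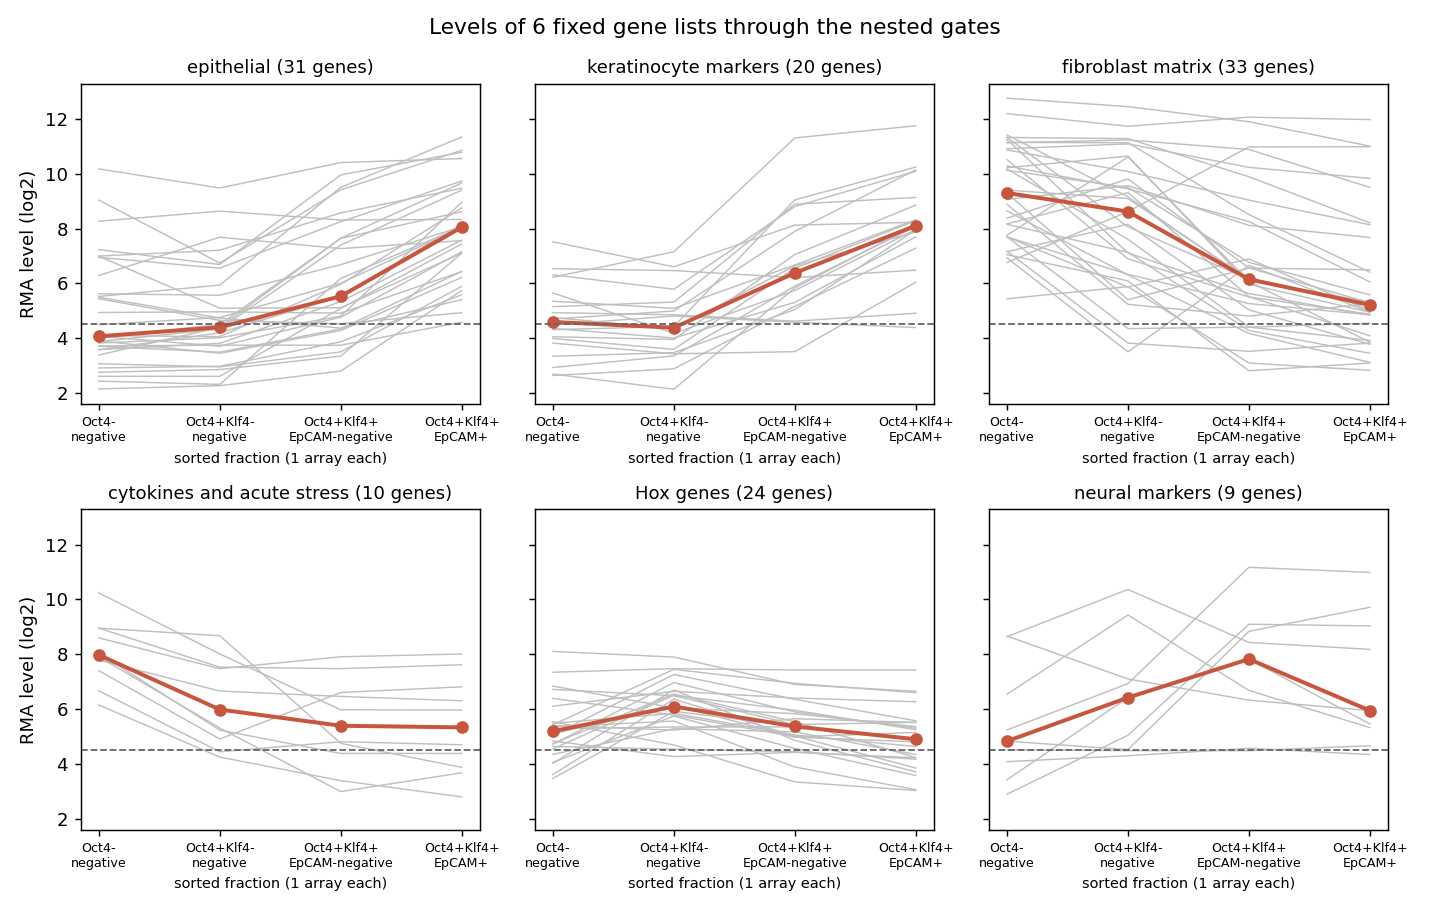
RMA level (log2) of the measured members of 6 fixed gene lists in the 4 sorted fractions, 1 array each, with grey lines for genes, the thick line for the list median and the dashed line at the floor of 4.53. The matrix median goes from 9.30 to 5.22 and the epithelial median from 4.07 to 8.04, while the Hox median is highest in the Oct4+Klf4-negative array, at 6.10.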

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

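All alternatives were chosen before the data were examined. No paired analysis was possible because each group holds 1 array. Quantile, cyclic loess and median normalization, the mean of all probe sets, and leaving out probe sets with shared sequence moved none of the 10 counts of genes by more than 1.5 times. The deposited columns were already RMA-processed, so normalizing them again could change little and is a weak check. Under each of these settings some list medians moved by more than 1.5 times while their call stayed the same. Median centring shifted the median of all genes to 0.14 in the comparison of the ends, from 0.07, and the share of calls that were higher from 52.4% to 55.7%. Signal over background limits the dim genes, and members below the floor decide several list medians. For each change of a call given here the cause was not tested, except where fewer or more features counted by construction.

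With the floor at the 75th percentile the counts of higher and lower genes were 191 and 303 at the Oct4 step, 495 and 443 at the Klf4 step, 162 and 59 at the EpCAM step and 797 and 731 between the ends. With a 3-fold threshold they were 201 and 279, 547 and 383, 150 and 75, and 798 and 684. Counting probe sets gave 863 and 1115, 1719 and 1681, 383 lower at the EpCAM step, and 2423 and 2745. A step of 0.25 gave 222 genes higher and 265 lower at each gate.

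At the Oct4 step, the early or broad pluripotency list lay within the random range with the mean of all probe sets (0.23), with no floor (0.00) and with the mean of its members (0.49), and so did the p53 and senescence list with the mean of its members (-0.24). The macrophage and leukocyte median reversed to 0.048 with no floor. At the Klf4 step, the mean of the members put mesenchymal regulators (-0.26) and p53 and senescence genes (-0.29) within the range. The cytokine list was within it with the higher floor (-0.52) or none (-0.056), and the Hox list with the higher floor (-0.90). The primitive endoderm and endoderm median reversed from -0.45 to 0.028 with no floor.

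At the EpCAM step, calls ended for contractile genes with the mean of all probe sets (-0.13) or the higher floor (-0.061), for the cell cycle without shared-sequence probe sets (0.036) or with the mean of members (0.058), for oxidative phosphorylation with the mean of members (-0.10) and for Hox genes with the higher floor (-0.34). Calls appeared for TGF-beta targets with the mean of members (-0.40), for interferon genes with the mean of all probe sets (0.25), for chromatin genes with the higher floor (0.091) or the mean of members (0.12), and for housekeeping genes without shared-sequence probe sets (-0.14). The primitive endoderm and endoderm median reversed from -0.78 to 0.059 with no floor. Between the ends, glycolysis was called with the mean of members (0.57), and chromatin genes were not with the mean of all probe sets (0.25) or of members (0.41). The Hox median reversed to 0.53 with the higher floor and lay within the range with the mean of all probe sets (-0.27), quantile (-0.28) or loess normalization (-0.27) and the mean of members (-0.38).

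With the mean of its probe sets, Epcam had log2 differences of 0.35, 0.93, 2.67 and 3.95 in the 4 comparisons. Klf4 had 0.47 at the Klf4 step and reversed to -0.24 between the ends, since its probe sets oppose each other. Laptm5 reversed without probe sets of shared sequence, where a probe set below the floor was left, to -0.45 at the Klf4 step and 0.38 at the EpCAM step.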

Other observations

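The counts of genes with an extreme in 1 gate, both tests of the Klf4 probe sets, both tests of the EpCAM-negative array and the second test of the neural genes were chosen after the values had been seen, and the neuronal list of the first neural test was written before it was looked up. The Oct4+Klf4-negative array held 208 genes that were at least 2-fold above both neighbouring arrays and 132 that were at least 2-fold below both. The 208 genes were 50.7% of those higher at the Oct4 step, where lists drawn independently would share 30.7 genes, although the shared array adds to such an overlap by an amount that 1 array per fraction leaves unknown. They included Itga1, with levels of 4.37, 8.75, 3.52 and 2.77 through the gates, Vgf, a secreted neuropeptide precursor (3.20, 7.25, 2.92 and 4.02), and the growth factor gene Igf1 (3.76, 7.18, 3.55 and 3.01). Among the 132 were Col6a3, with 6.93, 3.50, 6.66 and 4.95, the potassium channel gene Kcnn4 (8.62, 4.93, 8.93 and 9.19) and the stress-induced gene Nupr1 (8.72, 5.64, 8.87 and 9.19). The Oct4+Klf4+EpCAM-negative array held 39 genes 2-fold above both neighbours, led by Nts, and 13 below both.

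Several fixed lists moved little or held members that parted. The interferon list was not shifted between the ends (median log2 difference -0.30, percentile 4.07). Of its 12 measured members, 5 were higher in the Oct4+Klf4+EpCAM+ array and 4 lower. The higher ones included the class I antigen genes H2-K1 (log2 difference 3.85) and H2-D1 (3.09-fold). Each probe set of H2-K1 reaching the floor was higher, by a log2 difference of at least 1.459. The lower ones included Ifit2 (log2 difference -3.90), the peptide transporter gene Tap1 (8.65-fold) and the light chain gene B2m (2.11-fold). In glycolysis (median log2 difference 0.19, percentile 90.2) the lactate transporter gene Slc16a3 (7.57-fold), Aldoc (6.89-fold) and Hk2 (3.37-fold) were higher, Pfkm was 2.78-fold lower, and Ldha had a log2 difference of -0.12. With the mean of its members (0.57) the glycolysis list was called. Wnt targets were shifted down (median log2 difference -0.94, percentile 0.73) with 2 members lower, Tcf7l1 (2.78-fold) among them, and 2 higher, Lef1 (4.04-fold) among them. Adipocyte markers (median log2 difference -1.29, percentile 3.08) held Fabp4, 35.4-fold lower, and Pparg, 2.03-fold higher, and cartilage and bone markers (median log2 difference -1.12, percentile 3.61) held Col11a1, at least 8.58-fold lower, beside Alpl, 5.56-fold higher. The primitive endoderm and endoderm list was shifted down (median log2 difference -2.16, below all 10000 random lists) through the basement membrane genes Col4a2 (19.2-fold) and Sparc (8.64-fold), and Gata4, Gata6 and Sox17 did not reach the floor. Germ line genes (median log2 difference 0.12, percentile 54.5) held Piwil2, at least 4.17-fold higher, and skeletal muscle markers (median log2 difference 0.31, percentile 81.7) no gene past 2-fold. The macrophage and leukocyte list (median log2 difference -0.15, percentile 33.2), endothelial markers (median log2 difference 2.05, percentile 99.94), cell cycle (median log2 difference 0.48, above all 10000 random lists), immediate early genes (median log2 difference -0.11, percentile 9.33) and neural markers (median log2 difference 0.26, percentile 69.5) complete the comparison of the ends. Oxidative phosphorylation (median log2 difference -0.06, percentile 8.82), ribosomal proteins (median log2 difference -0.06, percentile 13.9) and housekeeping genes (median log2 difference 0.01, percentile 43.8) were not shifted. Of the erythroid markers only Hbb-y and Alas2 reached the floor, Hbb-y with levels of 8.95 and 7.86 in the Klf4-positive arrays and no more than 2.73 before and Alas2 with 5.41 to 4.89, and of the mesendoderm genes only Mesp1 (4.63 to 4.93).

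The 2 probe sets of Klf4 parted at the Klf4 gate, where the brighter was higher and the other lower. Scatter between probe sets is argued against as the cause, since opposite 2-fold differences at that step occurred in 0.035% of the 5708 genes with several probe sets, Klf4 and Zmynd8. A candidate explanation is an introduced Klf4 construct that lacks the part of the transcript read by the dimmer probe set, with the fibroblasts' own Klf4 transcript lower, and that probe set was lower in the Oct4+Klf4+EpCAM+ array than in the Oct4-negative array by a log2 difference of -3.75. The positions of the probes and the sequence of any construct are not in the sources used here, so this explanation and another change in transcript structure cannot be told apart.

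Epithelial and keratinocyte genes were higher in the Oct4+Klf4+EpCAM-negative array although its cells were sorted as lacking EpCAM. Carry-over of cells with the average profile of the EpCAM-positive fraction is argued against as the whole cause. On the linear scale Epcam stood at 8.06% of the way from the Oct4+Klf4-negative to the Oct4+Klf4+EpCAM+ level. The 43 listed genes at least 2-fold apart between those arrays stood at a median of 19.1%, 36 of them above Epcam. Because EpCAM was the sorted marker, carried-over cells low in EpCAM would also put other genes above Epcam. The shares cannot exclude carry-over of such cells. Among the 37 of these genes above the background ceiling on both EpCAM-negative and Klf4-negative arrays, the median was 22.7% and 32 stood above Epcam, while Rab25 (2.45%), Krt18 (0.31%) and Tjp3 (-1.89%) were among those below it, and no size was estimated for a smaller carry-over. The cells may instead have held part of an epithelial programme, under which the shares would differ between genes. The shares had an interquartile width of 18.9 percentage points, with Itga6 at 89.7%, Itgb4 at 83.1% and Krtdap at 72.4%. Carried-over cells low in EpCAM could also spread the shares, so this width does not decide between the 2. Itga6 had a level of 7.52 in the Oct4-negative array and 6.60 in the Oct4+Klf4-negative array, so its share rests in part on a low starting level. One array cannot show whether all cells of the fraction held such a programme or a part of them, and these cannot be told apart here.

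Neural genes were higher in the Oct4+Klf4-negative array, led by Cbln2, Nefl, Elavl2 and Nefm. Neurons carried over into the sort are argued against as the whole cause: of 27 abundant neuronal transcripts on the array, 7.41% (2, Syt1 and Elavl4) reached the floor and were at least 2-fold higher than in the Oct4-negative array. In that list 10 reached the floor in the Oct4+Klf4-negative array, 7 of them with a higher and 3 with a lower level than in the Oct4-negative array. Snap25 stayed at 2.35 there, below the background ceiling. The alternative was transcription of a part of the neural genes in the sorted cells themselves, under which abundant neuronal transcripts would not be higher as a set. The 12 that reached the floor on any array had a median log2 difference of 0.37, with quartiles of -0.25 and 0.88. Their median lay above the random range (percentile 99.2), a shift of these 12 that goes against this prediction. Over all 27, including those below the floor, the median log2 difference was 0.00, and 2 were at least 2-fold lower. The values therefore do not establish that alternative, and a smaller carry-over of neurons stays open. The higher neural levels were only in part particular to this array. The fixed neural list had median levels of 4.8, 6.4, 7.8 and 5.9 through the gates. Elavl2 had 8.54, 8.79 and 8.73 in the Oct4-positive arrays, while Cbln2 had 9.56, 4.79 and 3.23. For genes lower again at the Klf4 gate, Oct4 without Klf4, the amplification of this 1 sample and its culture cannot be told apart as sources with 1 array. The source of the levels that stayed high was not tested.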
